A study of Danio rerio with 2 samples.

How the data were processed

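The series held 2 RNA libraries from whole zebrafish embryos collected at 32 hours post fertilisation after growth at 28 °C, 1 from wild-type siblings and 1 from supt16h mutants. Per the labels' protocols, polyadenylated RNA was purified from 1 µg of total RNA, made into stranded libraries and sequenced as paired reads of 50 nucleotides. The number of embryos per library was not given in the sources used here.

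Gene values were used as the authors deposited them. The submitters' processing notes name CASAVA 1.8, TopHat2 2.1.1, Cufflinks 2.2.1, Cuffdiff and the Zv9 genome build, without roles or options. The deposited expression table has the columns of a Cuffdiff gene comparison, with 1 FPKM value per locus and library, per the file headers. Its log2 ratio, p-value and q-value columns are the authors' own comparison of 1 library against 1 library, and they are quoted only as the authors' deposited table. The deposited p-value matched the normal tail probability of the test statistic on both sides, within 0.001, at 100% of loci of status OK. A standard error of the authors' log2 change was therefore taken as that change divided by its statistic, with quartiles of 0.64 and 0.97 around the median of 0.74. Loci called in the authors' deposited table had q values up to 0.0470. The deposited variant table was annotated with SnpEff 3.1k per the file headers, and holds for each variant a quality score and a coverage, the count of reads at the site, as the authors deposited them. The variant caller, its filters and the library were not given in the sources used here. Quality scores ran from 10 to 227.

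Samples were grouped by their titles. Of 34728 loci, 20044 had status OK, 14666 NOTEST, 15 FAIL and 3 LOWDATA. Loci with status FAIL or HIDATA, or with a mean below 1 FPKM, were left out of counts and lists, which left 20638, and the limit on the mean removed 14075 loci. Differences were taken as log2(mutant FPKM + 1) minus log2(sibling FPKM + 1), a scale that understates the change of low genes, while values and folds in the text are the deposited FPKM and their ratios. The values were not scaled again. Their median log2 difference was 0.0012 over measured genes and 0.02 over the 8278 genes with a mean of at least 10 FPKM, with a robust spread of 0.60. With 1 library per group no test between genotypes was possible and no p-value was computed. Genes were counted at a fixed size of 2-fold on that scale, with 1 FPKM added. Exact (Clopper-Pearson) and Wilson intervals at 95% cover counting error only. Sequencing depth was not stated, and FPKM hides it, so the relative depth of the libraries was read from the smallest steps of values below 1 FPKM at 4528 loci. Of these, 24.2% fell on a common step within 0.02 on the log2 scale.

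Gene lists, the size rule and the main settings were written before the data were examined. The 27 lists covered FACT and histone chaperones, damage response and cell cycle arrest, replication, mitosis, apoptosis, Notch, neural progenitors, proneural genes and neurons, retina and lens, neural crest, pharyngeal arch and cartilage, pigment cells, erythroid cells, stem cells and leukocytes, endothelium, heart muscle, skeletal muscle, segmentation clock, notochord and floor plate, hatching gland with yolk and digestive organs, epidermis and ionocytes, ribosome biogenesis, ribosomal proteins, heat shock and unfolded protein response, circadian clock, interferon and inflammation, and histones. They held 969 distinct measured genes, 42 of the memberships matched through RefSeq synonyms. Each list's median was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and was called above or below when it left the central 95%. This describes the libraries and is no test of genotype. On simulated differences, lists of 50 genes shifted by 0.5, 1, -0.5 and -1 gave medians of 0.63, 0.99, -0.48 and -0.98 among 20638 genes. Of 600 unchanged simulated lists of randomly drawn genes with independent differences, 6.17% left the central range. A simulated depth ratio of 1.5 over 34728 loci was recovered as 1.5.

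Genes named in the text were supt16h, ssrp1a and ssrp1b, the 12 largest rises and 12 largest falls among genes with at least 5 FPKM in 1 library with a gene symbol (no clone or identifier name) that stands at 1 locus only, up to 4 members of each list with the largest difference, and variants in supt16h or of high predicted impact within 10 Mb of it. The text leaves out most of the small RNA genes that the size rule selects, and 5 list members with small differences (rpl7a, rplp0, rps26l, nkx2.2a and slc4a1b). The result for 1 further list member is not reported here. Other genes were named after their values were seen, among them mdm2, birc5a, elavl3, elavl4, snap25a, gad1b, rbpja, her6, dla, notch1b, jag1a, apoc2, apobb.1, fabp2, ptf1a, ela2, cntn2, he1a, he1b, ctslb, the cartilage matrix genes, c3a, the other members of the interferon list, the globins and haus3. Symbols are those of the deposited table or the list, and the table writes fos for fosab, coe2 for ebf2, cry1a for cry1aa and apobl for apobb.1. In the deposited files, 19 locus names and 4 gene names of variants read as dates, 468 variant entries for insertions or deletions had an unreadable allele, 2834 loci had no name and 440 carried several names. These loci were kept in genome-wide counts.

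A variant site was counted once, by its most severe annotation, from 10036 deposited entries of variant and transcript. A share of homozygous sites per library had been planned, and since every entry is marked homozygous, numbers of sites were used instead. Alternatives changed the pseudocount, the scaling, the limit on low values, the status, the fold threshold, the list summary, the interval around supt16h, the q limit, and the coverage, quality and window of variants. Alternatives added after the data were seen were a coverage of at least 10 reads, windows of 10 Mb per measured gene, list members matched by symbol only, list members of other lists left out, and the Notch list without its her4 copies. A reference genome was not used here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.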

Results

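RNA was measured in whole zebrafish embryos at 32 hours post fertilisation, in 1 library from wild-type siblings and 1 library from embryos mutant for supt16h. The gene supt16h encodes a subunit of FACT, the histone chaperone that takes nucleosomes apart and rebuilds them during transcription and DNA replication. The series was designed to map a mutation by linkage from the single nucleotide variants in the RNA. There were no replicates, so every difference below describes these 2 libraries and has no check against variation between embryos. The expression table held 34728 loci with 1 FPKM value per library, and 20638 of them had a mean of at least 1 FPKM and are called measured. FPKM summed to 1029580 over all loci in the sibling library and to 1095954 in the mutant library. The low FPKM values moved in steps, which placed the mutant library at 1.53 times the depth of the sibling library. The absolute depths were not recovered. A locus was listed at 0 in the sibling library alone in 1999 cases and in the mutant library alone in 678 cases.

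The first comparison asked whether supt16h and the genes of its partner differed between the libraries. Expression of supt16h was 44.4 FPKM in the sibling library and 2.98 FPKM in the mutant library, a level 14.9-fold lower. The gene lies on chromosome 7 from 1689456 to 1757060 of the Zv9 build. On the log2 scale with 1 FPKM added, the difference was -3.51. The authors' deposited table gives a log2 change of -3.90 for supt16h with an implied standard error of 0.69 and q = 4.38e-05, and that q compares these libraries, not the genotypes. The other FACT subunit is encoded by ssrp1a and ssrp1b. The levels of ssrp1a were 61.1 and 42.2 FPKM in sibling and mutant, and those of ssrp1b were 1.57 and 1.91 FPKM. Neither ssrp1 gene was called different in the authors' deposited table. Among 21 measured genes of FACT and other histone chaperones the median log2 difference was -0.52, below the central 95% of random lists (-0.29 to 0.33). Besides supt16h, 3 members were at least 2-fold lower in the mutant. They were atrx, a chromatin remodeller (80.9 and 23.8 FPKM), mcm2, a helicase subunit that also binds histones (48.4 and 15 FPKM), and anp32b (295 and 133 FPKM).

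The second comparison described the transcriptome as a whole. Of the measured genes, 1393 were at least 2-fold higher in the mutant (6.75%, exact 95% interval 6.41 to 7.10) and 1725 were at least 2-fold lower (8.36%, 7.98 to 8.74). These intervals cover counting only. The authors' deposited table calls 94 of 20044 tested loci different, of which 37 rose and 57 fell. The other 3026 genes that differed at least 2-fold were not called there. A 2-fold difference in this series therefore often lay within the error of the authors' model, whose implied standard error of a log2 change had a median of 0.74. Across measured genes the log2 levels of the libraries correlated with r = 0.856, a value across genes, which are not independent replicates.

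Among genes with a symbol that stands at 1 locus only, clone names left out, the largest rises and falls included isg15, fabp1b.1, helt, plp1a and atoh7. The ubiquitin-like interferon-stimulated gene isg15 rose from 0.221 to 32.2 FPKM in the authors' deposited table. The locus shared by fabp1b.1 and fabp1b.2, liver-type fatty acid binding proteins that the table does not separate, rose from 46.0 to 699 FPKM. Falls called in the authors' deposited table were helt, a repressor of the hairy and Enhancer-of-split type (26.3 to 0.469 FPKM), plp1a, a proteolipid protein of myelin (117 to 7.78 FPKM), atoh7, the proneural factor of retinal ganglion cells (30.8 to 1.79 FPKM), dre-mir-9-6 (119 to 5.78 FPKM) and supt16h. Genes of similar size that were not called were gria4b, a glutamate receptor subunit (3.30 and 92.5 FPKM), ptprz1a, a receptor tyrosine phosphatase (23.1 and 1.26 FPKM), and znrf2b, a ubiquitin ligase listed at 0 in the sibling library and at 13.2 FPKM in the mutant library. The remaining loci of the 24 selected by size were small RNA genes. Small RNA genes made up 15 of the 24, counting dre-mir-9-6, and 14 of these were listed at 0 in 1 of the libraries. Names that repeat in the table, dre-mir-9-7 among them, and genes with clone names, among them si:ch1073-382c16.2, which fell further than helt in the authors' deposited table (49.7 to 0.514 FPKM), were outside this ranking.

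**Figure D1:**
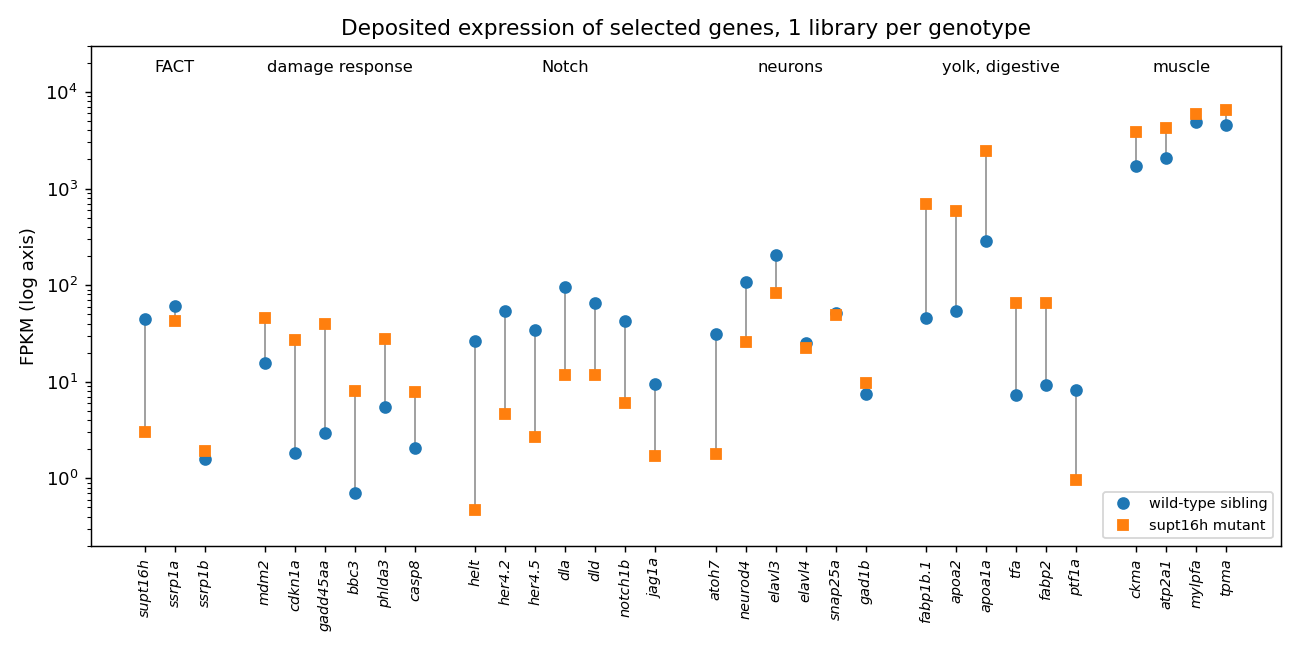
Deposited FPKM (log axis) of selected genes in the wild-type sibling library (circles) and the supt16h mutant library (squares), with a line joining the 2 values of each gene. The supt16h value falls from 44.4 to 2.98 FPKM, cdkn1a rises from 1.83 to 27.3 FPKM and helt falls from 26.3 to 0.469 FPKM, while snap25a stands at 51.8 and 49.2 FPKM.

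The list of damage response and cell cycle arrest genes included 4 of the genes called higher in the authors' deposited table. The cell cycle inhibitor cdkn1a rose from 1.83 to 27.3 FPKM (q = 0.00453), the stress gene gadd45aa from 2.95 to 39.3 FPKM (q = 5.06e-05), the pro-apoptotic gene bbc3 from 0.696 to 8.06 FPKM (q = 0.000432) and phlda3 from 5.41 to 27.8 FPKM (q = 0.0317), all q values from the authors' deposited table. The ubiquitin ligase gene mdm2 stood at 15.6 and 45.4 FPKM and was not called. Of 30 measured members, 7 were at least 2-fold higher and 0 at least 2-fold lower. The median of the list, 0.21, lay inside the random range (-0.27 to 0.26), while the mean of 0.58 lay above the range of random means. Of 25 measured apoptosis genes, 4 were at least 2-fold higher and 0 lower, and the median of 0.51 lay above the random range (-0.31 to 0.29). Without members shared with other lists the median was 0.31, inside the range. After bbc3, the members that differed most were casp8, the initiator caspase of the death receptor pathway (2.05 and 7.81 FPKM), bika (1.56 and 5.33 FPKM) and the casp6 locus (7.49 and 16.6 FPKM).

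Genes of DNA replication and mitosis were lower as groups in the mutant library. The 40 measured replication genes had a median of -0.59 against a random range of -0.20 to 0.25, and 11 of them were at least 2-fold lower and 0 higher. Thymidine kinase tk1, at a locus that also carries a second name, was listed at 182 and 34.3 FPKM, cyclin ccne2 at 43.2 and 12.2 FPKM and the ribonucleotide reductase subunit rrm1 at 174 and 52.9 FPKM. The 39 measured mitotic genes had a median of -0.44, also below their random range (-0.22 to 0.25), with 10 at least 2-fold lower and 1 higher. Topoisomerase top2a stood at 73.6 and 19.4 FPKM, cdca7a at 68.3 and 19.3 FPKM, cenpf at 17.2 and 5.02 FPKM and fbxo5 at 25.1 and 8.25 FPKM. The 1 member at least 2-fold higher was birc5a, a survivin of the chromosomal passenger complex (52.3 and 126 FPKM). The mitotic genes did not fall uniformly, with 30 below 0 and 9 above. Those above 0 included cdk1 (74.7 and 78.7 FPKM) and ccnb1 (231 and 276 FPKM). None of the replication or mitotic genes was called in the authors' deposited table. The 19 measured histone genes and their processing factors had a median of -0.27, inside the random range, and lay below it with 5 FPKM added (-0.24) or a mean of at least 5 FPKM (-0.33). The members that differed most were histh1l (459 and 188 FPKM), h1fx (42.5 and 18.1 FPKM), h2afx (113 and 51.4 FPKM) and h1f0 (203 and 102 FPKM).

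The Notch pathway was the lowest of the 27 lists. Its 35 measured members had a median log2 difference of -1.52, against a random range of -0.24 to 0.25, and 27 were at least 2-fold lower and 0 higher. The authors' deposited table calls 10 members lower. They were helt, the 5 her4 genes, which are direct Notch targets, the ligands dla (95.2 to 11.7 FPKM), dld (65.3 to 11.7 FPKM) and jag1a (9.46 to 1.70 FPKM), and the receptor notch1b (42.3 to 6.06 FPKM). Among the her4 genes, her4.2 fell from 53.4 to 4.67 FPKM, her4.5 from 34.3 to 2.7 FPKM and her4.3 from 34.8 to 3.42 FPKM. The her4 copies are near identical and lie next to each other on chromosome 23, so how their reads were divided is uncertain. Without them the median was -1.47. The transcription factor gene rbpja, through which the receptors act, stood at 14.2 and 14.9 FPKM, and her6 at 44.9 and 46.3 FPKM.

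Neural progenitor genes were lower as a group, with a median of -1.03 over 37 measured members, 19 of them at least 2-fold lower and 0 higher. The list shares 4 members with the Notch list. The receptors notch1a (67.7 and 8.75 FPKM) and notch3 (122 and 26.8 FPKM) and the eye and brain factor pax6b (34.5 and 6.02 FPKM) were not called, and her4.1 fell from 57.4 to 8.01 FPKM in the authors' deposited table. The notch1a locus is short, from 5088099 to 5088347 on chromosome 21. A longer locus beside it, NOTCH1 (2 of 3), is outside the lists and was looked up afterwards. It fell from 57.1 to 7.89 FPKM in the authors' deposited table (q = 0.00809). The combined list of proneural genes and neurons had a median of -0.49 over 53 members, 20 of them at least 2-fold lower and 0 higher. The proneural and early differentiation factors neurod4 (107 and 26 FPKM), atoh1a (14.5 and 2.89 FPKM) and ebf2 (86.3 and 21.1 FPKM) stood lower in the mutant. Genes picked as markers of differentiated neurons differed less. The synaptic gene snap25a stood at 51.8 and 49.2 FPKM, elavl4 at 25.3 and 22.1 FPKM and the GABA-synthesising enzyme gad1b at 7.48 and 9.65 FPKM. The pan-neuronal gene elavl3 (205 and 83.4 FPKM) and the axonal adhesion gene cntn2 (8.73 and 3.47 FPKM) were exceptions. In the retina and lens list the median was -0.55 over 47 members, 10 of them at least 2-fold lower and 1 higher. The retinal homeobox gene rx2 fell from 13.2 to 1.46 FPKM in the authors' deposited table (q = 0.0317), and vsx1 of bipolar cells (7.50 and 1.2 FPKM), rlbp1b (6.50 and 1.31 FPKM) and crx of photoreceptors (4.11 and 1.03 FPKM) were not called. Lens genes at least 2-fold lower included mipa (73.1 and 34.9 FPKM) and lim2.4 (104 and 48.6 FPKM), neither called. Among lens crystallins, crybb1 stood lower by less than 2-fold (428 and 313 FPKM) and crybb1l3 stood higher (3.47 and 5.55 FPKM). All 3 lists of this paragraph lay below their random ranges.

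**Figure D2:**
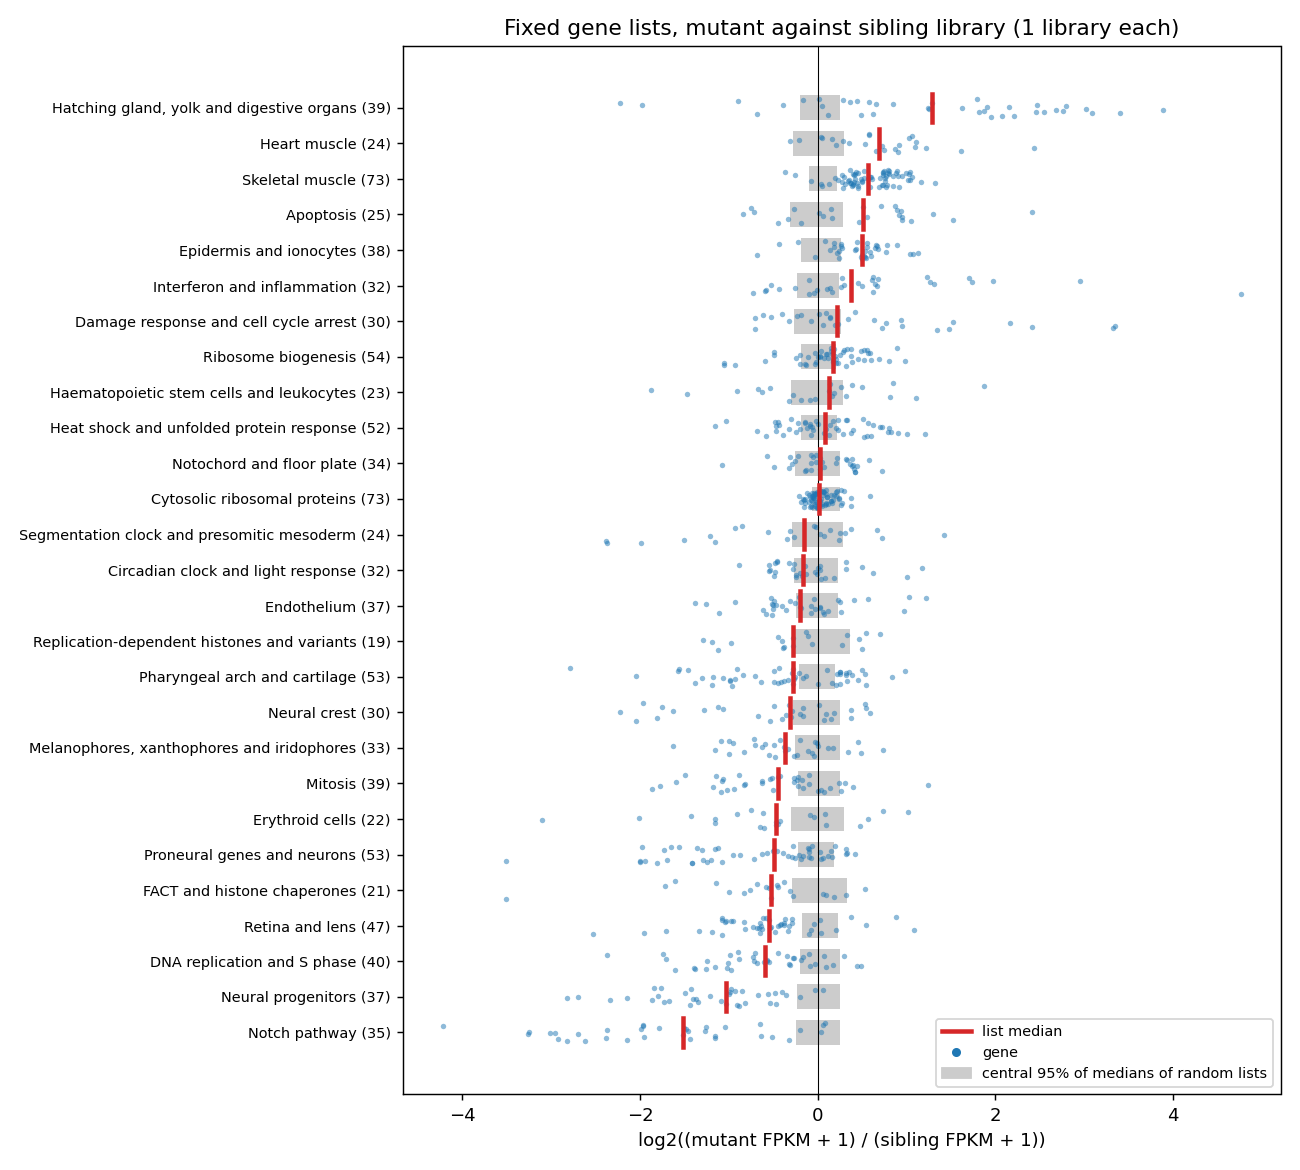
Log2 difference (mutant over sibling, 1 FPKM added) of the measured members of the 27 gene lists, with 1 point per gene, a red bar at the list median and a grey band for the central 95% of medians of random lists matched on expression. The Notch list has the lowest median (-1.52) and the list of hatching gland, yolk and digestive organs the highest (1.29), and ribosomal proteins sit near 0 (0.02).

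The lists of neural crest and its derivatives had lower medians by smaller amounts, and no member of these lists was called in the authors' deposited table. The neural crest list had a median of -0.31 (random range -0.28 to 0.25), with 9 of 30 members at least 2-fold lower and 10 above 0. It was led by pax3a (14.4 and 2.3 FPKM), sox9b (45.8 and 10.4 FPKM), cdh11 (21.5 and 4.77 FPKM) and tfap2e (15.0 and 3.58 FPKM). Its median lay inside the random range when 5 FPKM were added instead of 1, and when shared members were left out. The pharyngeal arch and cartilage list had a median of -0.28 (random range -0.21 to 0.20), with 10 of 53 members at least 2-fold lower, among them cyp26b1, which degrades retinoic acid (19.1 and 1.91 FPKM), alx1 (5.08 and 1.04 FPKM) and pou3f3b (99.6 and 33.0 FPKM). Cartilage matrix genes of that list differed in both directions. Those somewhat higher in the mutant included col2a1a (168 and 220 FPKM), col11a2 (25.7 and 37.6 FPKM), col9a2 (87.6 and 105 FPKM) and matn4 (101 and 127 FPKM). Those lower included col11a1b (11.8 and 6.15 FPKM), hapln1a (111 and 90.8 FPKM) and acana (3.31 and 2.73 FPKM). The pigment cell list had a median of -0.37 (random range -0.26 to 0.25), with 4 of 33 members at least 2-fold lower, namely pax7a (8.53 and 2.08 FPKM), trpm1b (14.4 and 5.91 FPKM), tfec (2.71 and 0.750 FPKM) and pmelb (27.6 and 13.3 FPKM). By its mean of -0.36 the pigment cell list lay inside the random range.

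In blood, the erythroid list had a median of -0.47, below its random range of -0.30 to 0.30, with 5 of 22 members at least 2-fold lower and 1 higher. The red cell anion exchanger slc4a1a fell from 46.9 to 4.56 FPKM in the authors' deposited table (q = 0.0291). The erythrocyte carbonic anhydrase cahz (28.5 and 6.32 FPKM), nt5c2l1 (5.79 and 1.52 FPKM) and the membrane skeleton gene epb41b (2.45 and 0.543 FPKM) were not called. The abundant embryonic globins hbbe1.1 (1817 and 1157 FPKM), hbae3 (1421 and 1043 FPKM) and hbae1 (942 and 679 FPKM) stood lower by less than 2-fold, and hbbe3 stood at 780 and 833 FPKM. Stem cell and leukocyte genes had a median of 0.13, inside the random range, and their members differed in both directions. The neutrophil genes npsn (20.6 and 4.89 FPKM) and lyz (63.3 and 22.2 FPKM) stood lower, and apoeb, which is also in the list of hatching gland, yolk and digestive organs (98.0 and 362 FPKM), and the myeloid factor cebpa (3.60 and 8.95 FPKM) stood higher. Endothelial genes had a median of -0.20, inside the random range, with gata2a at 11.3 and 3.73 FPKM, hey2 at 5.12 and 1.56 FPKM, fli1a at 12.4 and 5.20 FPKM and aplnrb at 6.24 and 15.9 FPKM.

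The list of hatching gland, yolk and digestive organs was the highest. Its 39 measured genes had a median of 1.29 (random range -0.19 to 0.25), with 22 at least 2-fold higher, 2 at least 2-fold lower and 7 called higher in the authors' deposited table. The lipoprotein genes apoa1a (287 to 2448 FPKM), apoa2 (54.5 to 586 FPKM) and apoc2 (16.4 to 117 FPKM), the apolipoprotein B gene apobb.1 (6.73 to 44.3 FPKM), the transferrin gene tfa (7.23 to 65.8 FPKM), the intestinal gene fabp2 (9.32 to 65.3 FPKM) and the fabp1b.1 locus rose there. The hatching enzyme genes he1a (44.3 and 191 FPKM) and he1b (18.6 and 89.6 FPKM) stood higher and were not called. Both are listed at the same coordinates, so the division of their reads is uncertain. The hatching gland gene ctslb (8.69 and 36.4 FPKM) also stood higher and was not called. The vitellogenin genes of this list were below the limit for measured genes. The 2 lower members were ptf1a, a factor of pancreas, hindbrain and retina (8.12 and 0.948 FPKM) and the elastase ela2 (5.10 and 0.550 FPKM), and neither was called.

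Muscle and epidermal genes were higher by a smaller amount. The heart muscle list had a median of 0.69 (random range -0.27 to 0.30), with 7 of 24 members at least 2-fold higher and 0 lower. The cardiac myosin light chain cmlc1 rose from 6.75 to 41.1 FPKM in the authors' deposited table (q = 0.0132), and vmhcl (4.05 and 14.5 FPKM), tnni1b (3.34 and 9.11 FPKM) and gata5 (0.969 and 3.25 FPKM) were not called. The skeletal muscle list had a median of 0.57 over 73 members (random range -0.10 to 0.22), with 7 at least 2-fold higher and 0 lower. Its members included the creatine kinase ckma (1704 and 3836 FPKM), the calcium pump atp2a1 (2068 and 4267 FPKM), ttna (10.5 and 23.0 FPKM) and tnnt1 (1.1 and 4.26 FPKM). The gene atp2a1 is listed at the same coordinates as hsp70 genes, so the division of their reads is uncertain. The epidermis and ionocyte list had a median of 0.50 (random range -0.18 to 0.26), with 3 of 38 members at least 2-fold higher and 0 lower, the annexins anxa1a (132 and 279 FPKM), anxa1b (42.3 and 88.0 FPKM) and anxa1c (243 and 535 FPKM). The interferon and inflammation list had a median of 0.38 (random range -0.23 to 0.24), with 8 of 32 members at least 2-fold higher, 0 lower and 3 called. In the authors' deposited table isg15, the immediate early gene fos (2.08 to 22.8 FPKM) and the complement gene c3a (0.697 to 4.54 FPKM) rose, and fosl1a (0.448 and 4.70 FPKM) and junba (1.45 and 7.21 FPKM) were not called. The other members at least 2-fold higher were junbb, socs3b and the complement gene cfb. Other interferon response genes were not among the 8, with gbp1 at 0.555 and 1.5 FPKM, irf9 at 2.27 and 4.05 FPKM, stat1a at 2.79 and 2.67 FPKM, stat2 at 2.56 and 1.14 FPKM, mxc at 1.21 and 1.07 FPKM and irf7 at 1.17 and 1.44 FPKM.

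The remaining lists lay inside their random ranges. Ribosome biogenesis genes had a median of 0.17, with nop56 at 163 and 78.0 FPKM, dkc1 at 54.1 and 25.6 FPKM, ncl at 238 and 125 FPKM and pes at 54.8 and 109 FPKM. Cytosolic ribosomal proteins had a median of 0.02, and 0 of 73 differed at least 2-fold, the largest difference being that of rps8b (1.15 and 2.22 FPKM). Heat shock and unfolded protein response genes had a median of 0.08, with the small heat shock gene hspb1 at 115 and 266 FPKM, hspb8 at 40.4 and 81.9 FPKM, the stress factor atf4b2 at 192 and 85.3 FPKM and its target trib3 at 28.5 and 13.4 FPKM. Circadian genes had a median of -0.16, with dbpb at 0.573 and 2.54 FPKM, the light-responsive cryptochrome cry1aa at 4.54 and 10.1 FPKM, nfil3-2 at 12.1 and 6.10 FPKM and cry-dash at 3.26 and 5.57 FPKM. Notochord and floor plate genes had a median of 0.03, with the matrix gene emilin3a at 6.54 and 2.57 FPKM, the notochord factor ta at 16.5 and 27.9 FPKM and ctgfa at 18.7 and 28.3 FPKM. Segmentation clock and presomitic mesoderm genes had a median of -0.15, although dld fell in the authors' deposited table and her12 (70 and 12.7 FPKM), her13 (48.5 and 11.5 FPKM) and hes6 (134 and 46.3 FPKM) stood lower. In all, 6 lists lay above, 11 below and 10 inside the central 95% of random lists. Of 27 lists of randomly drawn genes, 1.35 would lie outside on average. Genes of a fixed list can vary together, so that number is no yardstick for these lists. In addition, 49 genes belong to more than 1 list.

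The third comparison asked whether genes linked to supt16h differed more often than genes elsewhere, since mutant and sibling embryos can carry different haplotypes around a selected locus. Within 10 Mb of supt16h, 23 of 108 measured genes differed at least 2-fold (21.3%, exact 95% interval 14 to 30.2), 14 of them lower and 9 higher. On chromosome 7 as a whole the share was 17% (180 of 1060, 14.8 to 19.4), and on the other chromosomes it was 14.9% (2868 of 19184, 14.4 to 15.5). The share near supt16h lay above that of other chromosomes by an amount within its counting interval, and chromosome 7 ranked 3 of the 25 chromosomes after chromosomes 5 (21.7%) and 11 (19.4%). Named genes in the interval included vangl2, a planar cell polarity gene (42.6 and 18.1 FPKM), aldh1a3, a retinoic acid synthesis gene (2.75 and 0.805 FPKM), and the muscle actinin actn3b (81.5 and 170 FPKM). The pair arnt2 (15.6 and 5.71 FPKM) and MTHFS (5.60 and 12.9 FPKM) is listed at the same coordinates, so the division of their reads is uncertain. These 5 genes were chosen after their values were seen.

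The last comparison took up the linkage map, through the deposited list of variants. The list held 7447 sites, all marked homozygous, of which 7132 were single nucleotide variants and 315 insertions or deletions. The library in which they were called was not given in the sources used here, so the list describes where homozygous sites lie and does not compare the libraries. Coverage began at 2 reads and had a median of 4, and 46.8% of sites rested on 2 or 3 reads. Chromosome 7 held 418 sites (5.61%, Wilson 95% interval 5.11 to 6.16), number 4 among the chromosomes. Among the 1550 sites with at least 10 reads it held 140 (9.03%, 7.70 to 10.6), the highest number of any chromosome. Per 100 measured genes at that limit chromosome 7 held 13.2 sites and chromosome 1 held 15.5. Sites within 10 Mb of supt16h made up 1.68% of all sites (125, 1.41 to 2.0) and 3.61% of those with at least 10 reads (56, 2.79 to 4.66), while 0.528% of measured genes lie there. The first 10 Mb of chromosome 7 held 55 sites with at least 10 reads over 97 measured genes, or 56.7 sites per 100 genes. That density ranked 1 of 146 windows of 10 Mb with at least 20 measured genes, whose median was 6.05. The same window ranked 2 by number of sites with at least 10 reads, and 4 by all sites per gene. A window on chromosome 1 from 10000001 to 20000000 came next at 53.3. The other windows of chromosome 7 ranged from 2.34 to 17.9. By number of sites in windows of 1 Mb with no coverage limit, the choice made in advance, the window of supt16h held 19 sites and ranked 45 of 1155 windows with a site. The limit of 10 reads and the 10 Mb windows were chosen after the list was seen.

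**Figure D3:**
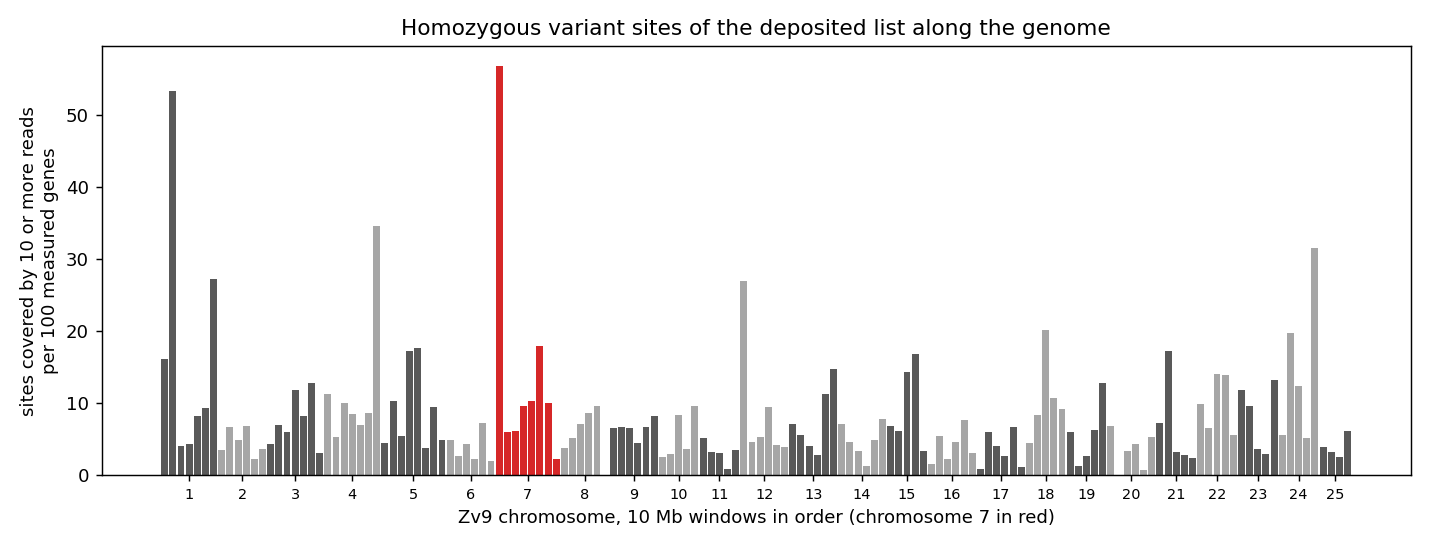
Homozygous variant sites covered by at least 10 reads per 100 measured genes (linear axis) in 10 Mb windows of the Zv9 chromosomes in order, with chromosome 7 in red. The first window of chromosome 7, which holds supt16h, is the highest at 56.7, and a window of chromosome 1 reaches 53.3.

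The deposited annotation placed 6 homozygous sites in the coding sequence of supt16h, 5 synonymous and 1 that creates a stop codon. The stop site is C1738164T on chromosome 7, the reference base first and the position counted on the forward strand of Zv9. It changes the codon Cag to Tag and gives Q501* in 2 annotated transcripts with a coding sequence of 3102 nucleotides and Q545* in the third, with 3234 nucleotides. It was covered by 12 reads with a variant quality of 222, and the 5 synonymous sites by 13 to 26 reads. Within 10 Mb of supt16h the list held 125 sites, of which 86 were annotated as synonymous and 25 as non-synonymous, 12 as lying in exons without a coding effect, 1 as intragenic and 1 as a stop. The supt16h stop was the only site of the high-impact classes (stop gained or lost, start lost, frameshift, splice site) in that interval. Chromosome 7 as a whole held 15 such sites and the genome 367, and the next on chromosome 7 lay 23.8 Mb away in haus3, a frameshift with a quality of 18.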

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

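Settings with a coverage of at least 10 reads, windows of 10 Mb, symbol matches only, shared members left out or her4 copies left out were chosen after the data were seen. With 5 FPKM added, the supt16h difference was -2.63, genes at least 2-fold higher or lower numbered 617 and 796, and the shares near supt16h and on chromosome 7 were 10.19% and 7.64%. With 0.1 FPKM added the share on chromosome 7 was 23.0%. A mean of at least 5 FPKM left 828 higher and 1296 lower genes. At 1.5-fold there were 3317 higher and 3799 lower genes, with shares of 38.0% near supt16h and 34.2% on chromosome 7. At 4-fold there were 441 and 368, so that higher genes became the larger group. No limit on low values gave shares of 10.6% near supt16h and 11.2% on chromosome 7, the opposite order to that of the main setting. A q of at most 0.01 left 21 higher and 33 lower calls of the authors' deposited table. Stricter limits and larger pseudocounts lower such counts by construction. Of 271 alternatives for list medians, 264 kept their place against the random range. The exceptions were damage response genes summarised by their mean (0.58, above), pigment cells by their mean (-0.36, inside), apoptosis without shared members (0.31, inside), neural crest with 5 FPKM added (-0.16, inside) or without shared members (-0.30, inside), and histones with 5 FPKM added (-0.24, below) or a mean of at least 5 FPKM (-0.33, below). Their cause was not tested. Chromosome 7 held 9.03% of variant sites at 10 reads, 9.24% at 20 reads and 6.86% at a quality of 50, and the 10 Mb around supt16h held 3.61%, 3.88% and 2.42%. The rank of chromosome 7 by number of sites was 1 at 10 and at 20 reads. Per measured gene its rank was 9 over all sites and 2 at 10 and at 20 reads. The window of supt16h ranked 14 at 5 Mb, 5 at 10 reads, 9 at 20 reads, 17 at a quality of 50, and 1 in 10 Mb windows per measured gene at 10 reads. Counted once per site, high-impact variants numbered 367, with 1 within 10 Mb of supt16h, against 592 and 3 entries per transcript, and at 20 reads there were 0, since 12 reads cover the supt16h stop. Why the ranks moved was not tested. The share of 2-fold genes that were higher was 44.7%, and 38.3% with each library rescaled to the same sum, while among 4-fold genes it was 54.5%. The shallower sibling library limits genes near 0. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out.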

Other observations

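All tests of explanations in this part were chosen after the results were seen. Loci that carry miR-9 genes, whose microRNA acts in neural progenitors, were low in the mutant library as a family. Taking at each position the annotated transcript with the most expression, 7 of 7 dre-mir-9 loci were lower, with log2 differences from -3.17 to -6.23, and 4 of them were called lower in the authors' deposited table. The largest was dre-mir-9-7, at 177 and 1.37 FPKM, with q = 0.0502 in the authors' deposited table and so not called. Those called were dre-mir-9-6 (119 to 5.78 FPKM), dre-mir-9-1 (30.9 to 1.57 FPKM), and the transcripts at the positions of dre-mir-9-5 (125 to 6.34 FPKM) and dre-mir-9-4 (48.6 to 2.17 FPKM). These loci span long transcripts with a poly(A) tail, so the values describe host or primary RNA and not mature microRNA. Of the 94 loci called in the authors' deposited table, 19 have no gene name, and 15 of those fell. A cluster of 4 on chromosome 11 has a her15 gene, one of a family of Notch targets, as its nearest named gene, 28617 to 65957 bases away, with FPKM of 95.9 to 7.41, 61.5 to 6.23, 112 to 11.4 and 62.2 to 10.

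Genes outside the lists that fell in the authors' deposited table, named here after their values were seen and grouped by no test, included gsx1 (43.6 to 6.83 FPKM), gsx2 (15 to 2.17 FPKM) and dbx1b (32.2 to 4.17 FPKM), homeobox genes of neural tube progenitors, the nuclear receptor gene rorb (13.4 to 1.89 FPKM), sox12 (14.6 to 1.99 FPKM), and the leucine-rich repeat gene lrrn1 (273 to 46.2 FPKM). The planar polarity cadherin celsr1b (8.10 to 1.49 FPKM) and the receptor ephb2b (9.87 to 2.08 FPKM) fell as well. Genes outside the lists that rose there included the secreted plasma protein fetub (5.53 to 49.2 FPKM), pla2g12b of lipoprotein secretion (6.10 to 44.4 FPKM), the muscle AMP deaminase ampd1 (0.426 to 4.54 FPKM) and the parvalbumin pvalb9 (22.2 to 121 FPKM).

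The fall of the Notch list was set against 3 other readings. A scaling factor of the libraries moves every gene alike and so cannot set 1 list apart. The Notch median lay -1.52 from that of all measured genes (bootstrap 95% interval over genes -2.0 to -1.26). Since the median of all measured genes was 0.0012, this distance restates the fall for which the list was taken up. It is no separate test. For 26 genes picked as markers of differentiated neurons, an equal loss of all neural cells is argued against. The Notch median lay -1.41 from theirs (-2.01 to -1.11), which was -0.10. They were taken from the list of 53 proneural and neuronal genes, whose median was -0.49. Genes left out included tubb5 (-0.72), mnx2a (-0.95) and lhx1a (-1.73), and also pou4f1 (0.33), so the gap depends on the choice of markers. The gap to the replication list was -0.93 (-1.64 to -0.57). The Notch list was taken up as the lowest, so the sign of that gap was set beforehand. It therefore does not decide on an equal loss of dividing cells in all tissues. A loss of dividing neural cells in particular cannot be judged by that gap, since the replication list covers the whole embryo. A loss of neural progenitors or of Notch signalling that spares neurons already formed may remain as a hypothesis, and the 2 cannot be separated in RNA of whole embryos.

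The rise of the list of hatching gland, yolk and digestive organs might reflect a smaller share of neural RNA in the mutant, which would raise all other tissues alike. Its median exceeded that of 132 muscle, heart and epidermis genes, which was 0.53, by 0.75 (bootstrap 95% interval over genes 0.04 to 1.42). The list was taken up as the highest, so the sign of this gap was set beforehand and the gap does not decide the question. The other tissues did not move alike, since the list medians of notochord (0.03), endothelium (-0.20) and erythroid cells (-0.47) stayed below those of heart muscle (0.69) and epidermis (0.50). A different developmental pace of the mutant cannot be told apart from the genotype, because the number of stages collected was 1. The lower members ptf1a and ela2 stood at 0.948 and 0.550 FPKM in the mutant against 8.12 and 5.10 FPKM, and since neither was called and ptf1a is also expressed in hindbrain and retina, what they say about the pancreas is left open.

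The fall of supt16h mRNA could come from decay of an RNA with an early stop codon, a hypothesis that these tables do not decide. A linked haplotype that lowers the whole neighbourhood is argued against, since 22 measured genes within 1 Mb had a median log2 difference of -0.045 (bootstrap 95% interval -0.27 to 0.19). Whether stop codons in the variant list go with lower mRNA cannot be told, since 16 other measured genes with a listed stop had a median of 0.26 (range of random lists -0.39 to 0.33) and only 3 of those stops rested on at least 10 reads. All 6 supt16h sites are C-to-T or G-to-A, 5 of them synonymous, against 34.7% of single nucleotide sites of all annotation classes. The 6 lie in 1 gene and are not independent, so nothing about their origin was read from this.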
